A study of Sinorhizobium meliloti with 4 samples.

How the data were processed

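From S. meliloti RmP110 in exponential phase 4 RNA libraries were sequenced, 2 of cells grown with 20 µM and 2 with 2 mM inorganic phosphate. Per the labels' protocols, total RNA was isolated with hot phenol and treated with DNase I, rRNA was removed in repeated rounds of hybridisation capture, RNA was fragmented with zinc, and adapters were ligated so that strand is kept. Reads were 34 nt long, per the labels. Groups were taken from the culture condition in the labels, and replicate numbers follow the order of the samples. Nothing in the sources used here says whether the libraries of a condition came from separate cultures.

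The authors deposited a signal for each base and strand of each replicon: counts of 5′ ends of perfectly matching reads, corrected for multiplicity, normalized, and pooled over both replicates, per the file headers. What set the normalization factor is not stated. The aligner, the genome build and the annotation are not given in the sources used here, and coordinates are those of the deposited files. The authors also deposited counts of reads per library in classes by match: perfect, single mismatch, matched by Blast and unmatched, per the file headers.

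Values at positions of multiplicity 1 were multiples of a step of 1.026 in the low and 0.7534 in the high phosphate columns. Dividing by these steps and multiplying by the multiplicity gave whole numbers within 0.02 for 100% of values. The sums were 9746888 and 9457924, against 9746879 and 9457879 perfectly matching reads in the deposited counts. Replicate 1 makes up 32.9% of the low and 32.6% of the high phosphate pool by those counts. The right end of a 34-mer was taken as the read start on the minus strand, which the multiplicity columns bore out at 100% of tested positions.

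No genome of this strain was used apart from the bases in the deposited files. ORFs were called on them with Prodigal 2.6.3, giving 6303. Names come from a gene table for another strain (assembly ASM3006458v1, strain CCBAU 71714), whose coordinates gave only gene lengths and spacing. An ORF took the name of a table gene of identical length where at least 3 neighbours also had identical lengths and were spaced alike within 15 nt (4435 ORFs). Neighbours were searched among the 6 on each side. Other ORFs took a name where they shared a stop codon between such ORFs (465). Of these 4900, 1040 have a symbol. Shuffled lengths gave 0 matches in 5 runs, and 14 of 14 symbols with a known protein signature carried it. ORFs without a symbol have a running number with C, A or B for chromosome, pSymA or pSymB. A protein signature is named where an ORF has one. Of the 16 genes fixed by name, 6 had a symbol in the table, and PstS and PiT were found by signature. The others (phoC, phoD, phoE, phoT, phoX, btaA, sqdB and plcP) had no symbol there. Whether they are among the ORFs that carry another name or no symbol was not checked.

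Sense reads were summed per ORF, divided over repeats as deposited. ORFs in the 3 rRNA operons or over placed RNA genes were left out (6). Ratios are log2 of low over high phosphate on the authors' scale with 0.5 reads added per pool, for ORFs with at least 80 reads over both pools (a mean of 20 per library). The 95% interval is the exact Clopper-Pearson interval of the split of reads. Where a pool had 0 reads, the ratio was computed against a floor of 3 reads. Shares have Wilson intervals. Counting error in simulated pools with 200 changed ORFs among 3084 measured put 1 of 2884 unchanged ORFs past 2-fold; all 50 ORFs simulated at 4-fold and 21 of 50 simulated at exactly 2-fold passed it.

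The planned edgeR test on 4 libraries could not be run, because the values are pooled over replicates; the ratio with its interval took its place and no p-value for transcripts is given. For the same reason the planned set tests were replaced by percentiles among 10000 random lists of ORFs drawn singly within 20 bins of read number. Fisher's test of PHO boxes had been planned on genes that rose in the edgeR test. It was replaced by the rank among 419 shuffled half-sites of CTGTCAT, spaced by 4 nt, although counts of ORFs past 2-fold would have allowed it. The 16 gene lists were fixed before the data were examined and matched by symbol only, so ORFs without a symbol are in no list. Named genes were fixed by rule at the same time: the 16 names, the 10 highest and 10 lowest ORFs, up to 3 per list past 2-fold, and up to 3 each way for antisense and gaps. The rule's conditions on p-values and single libraries could not apply. Further list members and neighbours (such as pstA, pstB, both pieces of pstC, the second phnE and ORF C189) were named outside the rule after their values were seen. Alternatives were other scalings, filters, pseudocounts, unique or distinct positions and strand. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.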

Results

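Directional RNA sequencing was carried out on Sinorhizobium meliloti RmP110, a soil bacterium that fixes nitrogen in root nodules of legumes such as alfalfa. Cultures in exponential phase had grown in MOPS-buffered minimal medium with 20 µM inorganic phosphate (low phosphate) or 2 mM inorganic phosphate (high phosphate). Each condition had 2 libraries, and the contrast asks how transcription differs when phosphate is limiting. The genome of this organism consists of a chromosome of 3654135 nt, the megaplasmid pSymA of 1354226 nt and the chromid pSymB of 1683333 nt.

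The libraries of low phosphate replicates 1 and 2 held 3898562 and 8390175 reads, and those of high phosphate replicates 1 and 2 held 4149349 and 9123537 reads. Reads without a match to the S. meliloti genome made up 9.94% and 11.8% of the low phosphate libraries and 18.1% and 20.6% of the high phosphate libraries. The difference between the condition means was -8.42 percentage points, with 10.9% ± 1.34 (SD, n = 2) in low phosphate and 19.3% ± 1.77 (SD, n = 2) in high phosphate. An exact two-sided permutation test gave p = 0.333 with n = 2 per group, which is the smallest value that 2 libraries against 2 can give. Within the prefixes GEA and HEA of the library titles, whose meaning is not stated, the differences were -8.12 and -8.73 percentage points. An exact sign-flip test of these 2 differences, chosen after seeing the data, gave p = 0.5, the smallest value possible. Perfectly matching reads made up 80.1% ± 2.96 (SD, n = 2) of the low phosphate libraries and 72.1% ± 3.06 (SD, n = 2) of the high phosphate libraries.

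The deposited values per base pool both replicates of a condition. They correspond to 9746888 perfectly matching reads in the low phosphate pool and 9457924 in the high phosphate pool. The transcript comparisons therefore set 1 pool against 1 pool, the differences have no replicate check, and no p-value for transcripts is given. Intervals in brackets are 95% intervals for counting error in these pools only, computed as if reads were independent. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow. Ratios are log2 of low over high phosphate, so positive values mean higher in low phosphate.

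Transcripts for phosphate acquisition were far higher in low phosphate, while transcripts for ribosomal proteins and for a permease of the PiT family were far lower. The highest ratios belonged to phnC and phnD, which encode the ATPase and the binding protein of a phosphonate-type ABC transporter on pSymB, at 10.66 and 10.64. All 9 measured members of the list for phosphate sensing and uptake were at least 2-fold higher, with a median of 5.61 (3.57 with distinct start positions). The list was matched by symbol. It therefore leaves out 2 ORFs without a symbol: ORF C512 with the PstS signature, at 6.67, and ORF C188 with the PiT signature, at -6.86. All 51 ribosomal protein ORFs were at least 2-fold lower, with a median of -3.33 (25 of 50 and -1.02 with distinct start positions). Of 3069 open reading frames (ORFs) with at least 80 sense reads over both pools, 533 were at least 2-fold higher in low phosphate, 695 were at least 2-fold lower and 1841 lay within 2-fold. For 344 of the higher and 435 of the lower ORFs the whole interval lay beyond 2-fold.

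These counts rest on the authors' scaling of the pools. With rRNA and tRNA kept in the library sizes, the median over all measured ORFs moved by -0.49, the higher ORFs numbered 325 and the lower ORFs 1168, and the share of higher among all such ORFs was 21.8% in place of 43.4%. With the totals of ORF sense reads, a scaling chosen after seeing the data, the median moved by 0.15, the higher ORFs numbered 625, the lower ORFs 592 and the share was 51.4%. Counts of distinct start positions, which saturate in ORFs dense with reads, gave 400 higher and 456 lower ORFs. With them 37 of the 57 named ORFs moved by more than 1.5-fold, all 37 toward 0, among them ORF C512 to 2.11 and rplL to -1.20. With both strands summed 8 named ORFs moved that far toward 0: phnC to 9.81, ORF C3152 to 7.58, phnE (ORF B854) to 7.34, ctaD (ORF C2566) to 4.45, phnK to 3.42, exoH to 2.71, ORF C1156 to -4.48 and ORF C188 to -4.36.

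The phosphonate-type transporter genes lie side by side on the minus strand of pSymB, and reads from all of them were scarce in high phosphate. Their names come from the table of the other strain. Whether they are the genes fixed by name as phoC, phoD, phoE and phoT was not checked. For phnC (923271 to 924110) the pools held 2975 reads in low and 2 in high phosphate, a log2 ratio of 10.66 (9.13 to 14.03). For phnD (922274 to 923179) they held 17024 and 14 reads, a ratio of 10.64 (9.95 to 11.56). The permease genes phnE (ORF B854), at 921140 to 922102, and phnE (ORF B853), at 919613 to 921130, had ratios of 7.99 (7.18 to 9.12) and 7.09 (6.51 to 7.82).

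The pst region of the chromosome, which encodes the high-affinity phosphate transporter and the regulators PhoU, PhoB and PhoR, was higher along its whole length. The most abundant ORF there was ORF C512 (566715 to 567749), which carries the sequence signature of PstS, the periplasmic phosphate-binding protein. It held 35516 reads in low and 475 in high phosphate, a ratio of 6.67 (6.54 to 6.80). In the deposited sequence the reading frame of the permease gene pstC is split into ORF C513 and ORF C514, with ratios of 5.91 (5.28 to 6.71) and 5.38 (4.96 to 5.86). The second permease gene pstA had a ratio of 5.61 (5.34 to 5.89), and the ATPase gene pstB one of 3.95 (3.77 to 4.14). Ratios were 4.93 (4.69 to 5.19) for phoU and 5.23 (4.86 to 5.65) for phoB, the response regulator of the phosphate regulon. The sensor kinase gene phoR (565258 to 566520), just upstream, had the smallest ratio of the region at 2.06 (1.56 to 2.61), from 130 and 42 reads.

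**Figure D1:**
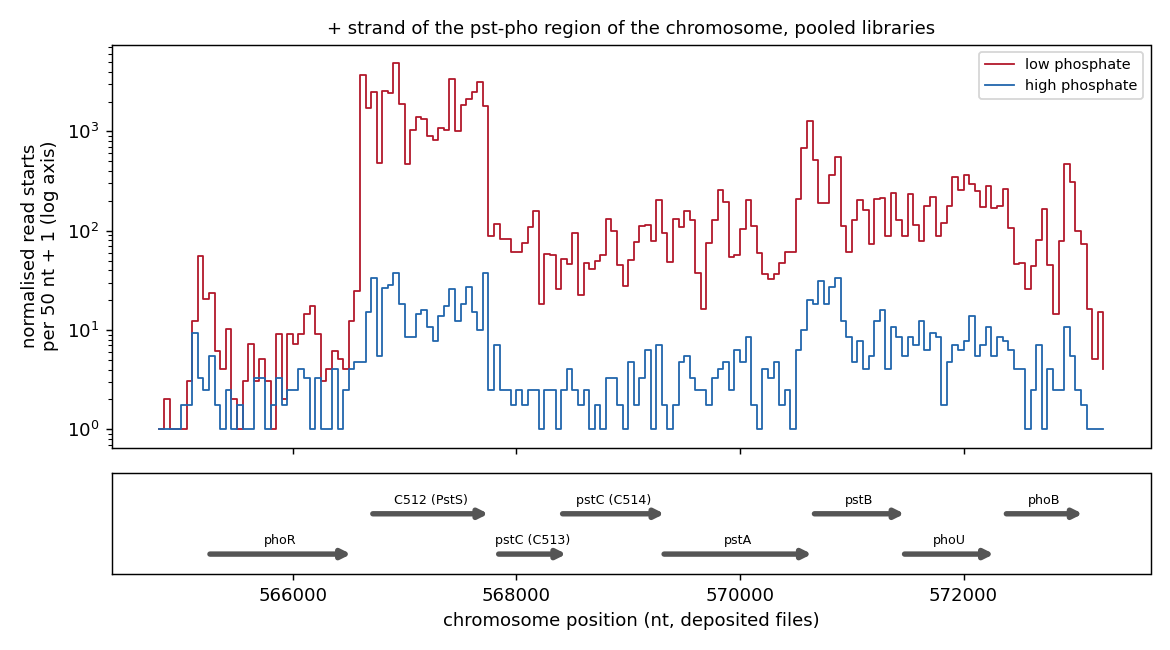
Normalised read starts on the plus strand of the pst region per 50 nt (log axis, 1 added), in the pooled low phosphate and pooled high phosphate libraries, above the ORFs drawn to scale along the chromosome. The pools held 35516 and 475 reads in ORF C512, and 130 and 42 reads in phoR.

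Among the 10 ORFs with the highest ratios, 7 carried no symbol in the names table. ORF C3152 (3351886 to 3353448) had a ratio of 9.53 (8.20 to 12.03) from 1898 and 3 reads. ORF C1209 (1293997 to 1295355), next to the exopolyphosphatase gene ppx, had a ratio of 9.26 (8.71 to 9.93). ORF C1873 (1992362 to 1993207), with a metallophosphoesterase signature, had a ratio of 8.80 (7.61 to 10.85) from 1477 and 4 reads. Of the 5 measured ORFs with that signature it was the only higher one, and 3 were lower. ORF C2239 (2367262 to 2367927) had 676 reads in low and 2 in high phosphate, a ratio of 8.53 (6.99 to 11.90). ORF C3026, ORF C1281 and ORF C1108 combined high abundance with high ratios: 12393, 13906 and 18145 reads in low phosphate and ratios of 8.30, 8.22 and 8.16.

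PHO boxes, the direct repeats bound by PhoB, were more frequent upstream of the ORFs that were higher in low phosphate. A box with at most 4 mismatches of 14 lay within 250 nt upstream of 53 of 533 higher ORFs, 9.94% (Wilson interval 7.68 to 12.8%), and of 117 of 2536 other measured ORFs, 4.61% (3.86 to 5.50%). The share was 29.2% (18.2 to 43.2%) among the 48 ORFs at least 32-fold higher. The ratio of the shares was 2.16, and none of 419 shuffled half-sites gave a ratio as large. The highest of these was 1.64. With 5 mismatches allowed the ratio was 1.14, and 22 of the 419 shuffled half-sites reached it. Of the named ORFs, ORF C1281 had the closest match, CTGTCATCCAGCTGTTAC at 1367797 to 1367814 on the chromosome, with 2 mismatches and 81 nt from the start codon. ORF C512 had CTGTCATAAATGTTTCAC at 566583 to 566600, katA had CTGTCGTTCAGCCGTCAC at 840244 to 840261, and phnC had CTGACACTGCGCTTTCAT at 924173 to 924190 on pSymB, each with 3 mismatches.

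**Figure D2:**
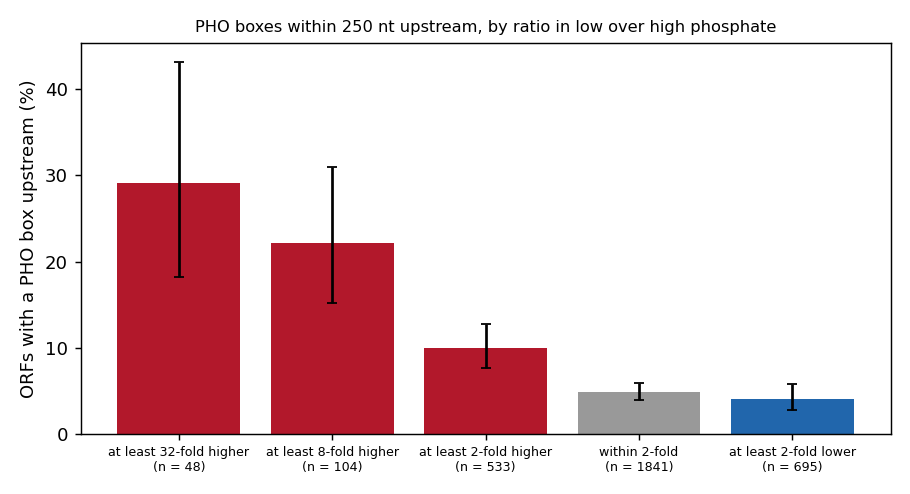
Percentage of ORFs with a PHO box within 250 nt upstream (bars) with 95% Wilson intervals (lines), for ORFs grouped by their ratio in low over high phosphate; n is the number of ORFs. The bars range from 29.2% among ORFs at least 32-fold higher to 4.03% among ORFs at least 2-fold lower.

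Other lists that were higher in low phosphate concerned organic phosphorus, exopolysaccharide and carbon storage. In the list for organic phosphorus use, 5 of 7 measured members were at least 2-fold higher and none lower, with a median of 3.20. With distinct start positions 3 of 6 were higher, with a median of 1.81. They included the carbon-phosphorus lyase genes phnK, with a ratio of 4.92 (3.94 to 6.35), and phnH, with 4.56 (3.42 to 6.35), and phnN with 3.32 (2.83 to 3.88), each from fewer than 40 reads in high phosphate. Of 15 measured members of the list for succinoglycan (EPS I), an exopolysaccharide needed for nodule invasion, 11 were higher and none lower, with a median of 2.61. The largest ratios were those of exoM at 3.83 (2.92 to 5.08), exoH at 3.36 (2.71 to 4.14) and exoK at 3.36 (2.77 to 4.06). Among 11 measured genes of carbon storage, 8 were higher and none lower, with a median of 1.25, against 6 with distinct start positions and a median of 1.06. The phasin genes phaP2 and phaP1, whose products coat polyhydroxybutyrate granules, had ratios of 4.42 (4.25 to 4.60) and 3.32 (3.07 to 3.58), and phbB had 2.46 (2.27 to 2.65). Medians of these 3 lists stood at the 100th, 100th and 99.9th percentile among medians of 10000 random lists matched on reads, as did that for phosphate sensing and uptake at the 100th. The random lists drew ORFs singly, while list members such as exoH to exoP or the pst genes lie in runs of neighbours. These percentiles thus treat neighbouring ORFs as separate draws and overstate how unusual the lists are.

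Single genes stood out in 3 further lists. The catalase gene katA (840311 to 841795) had 2157 reads in low and 48 in high phosphate, a ratio of 5.92 (5.52 to 6.38), while the other 4 measured genes for oxidative stress ranged from -1.65 for trxA (ORF C3252) to -0.34 for gor. In the list for membrane lipids without phosphorus, olsB was higher, at 5.51 (5.14 to 5.93), and olsA lower, at -1.27 (-1.79 to -0.79), although both act in ornithine lipid synthesis. Of 13 measured genes for ATP synthase and respiratory complexes, ctaD (ORF C2566), a cytochrome oxidase subunit gene, was higher at 5.05 (3.92 to 6.83) from 133 and 5 reads. The second copy, ctaD (ORF C916), had -0.46. The ATP synthase genes atpA and atpD were lower, at -2.10 (-2.18 to -2.03) and -1.75 (-1.83 to -1.68), but within 2-fold at -0.41 and -0.30 with distinct start positions.

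**Figure D3:**
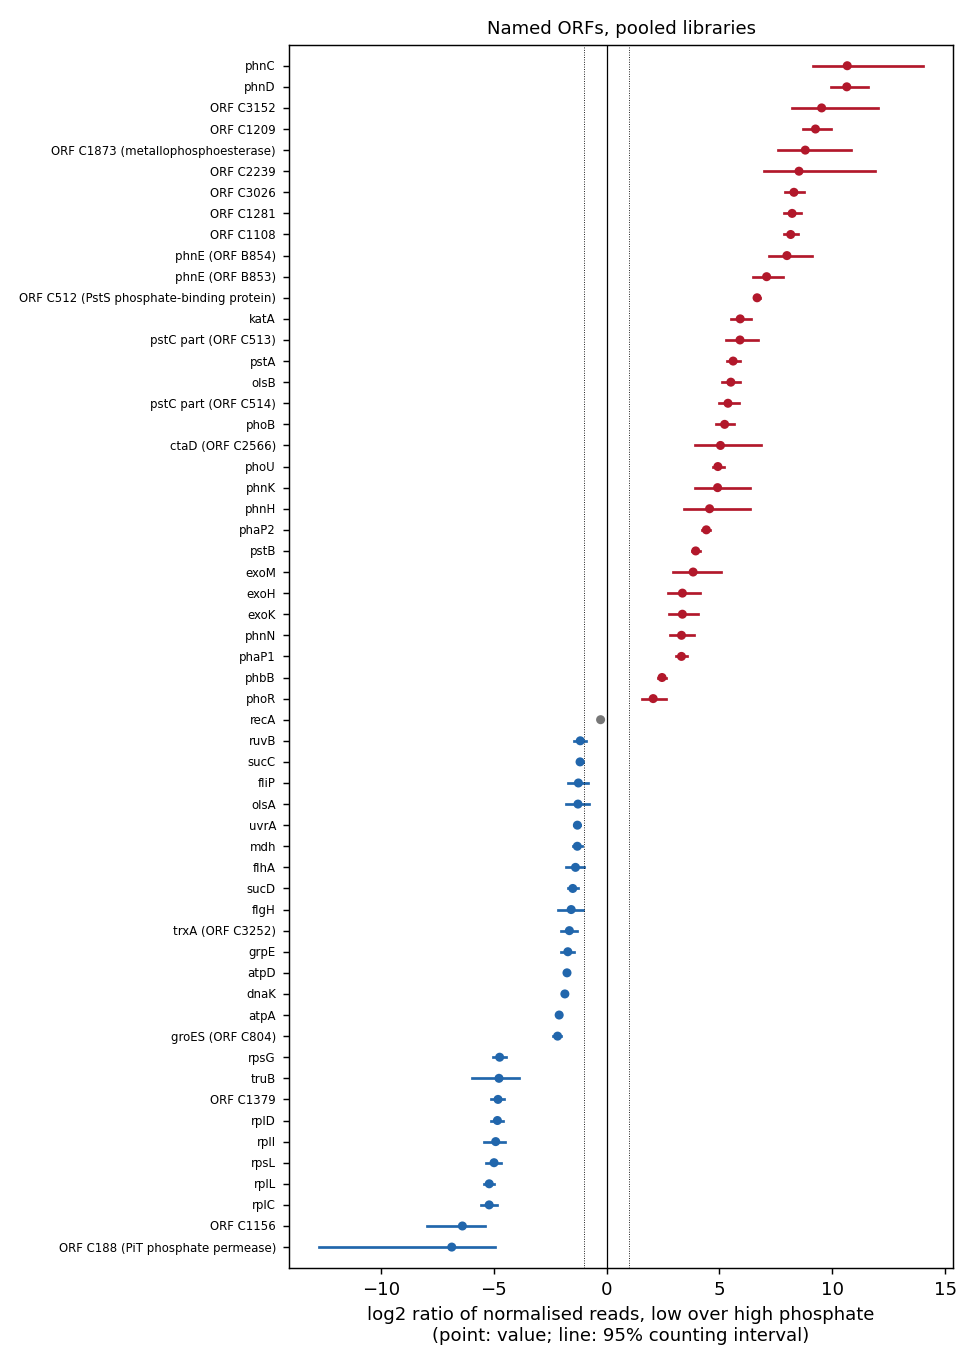
Log2 ratio of normalised reads in low over high phosphate (points) with 95% counting intervals (lines) for the named ORFs, pooled libraries; dotted lines mark 2-fold and red, blue and grey mark higher, lower and within 2-fold. Values run from 10.66 for phnC to -6.86 for ORF C188.

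The lowest ratio was that of ORF C188 (214914 to 215918, chromosome, minus strand), which carries the signature of the PiT family of phosphate permeases. It held 1 read in low and 237 in high phosphate, a ratio of -6.86 (-12.75 to -4.95). With both strands summed its ratio was -4.36, and rplL at -5.20 was the lowest named ORF. With 5 reads added it was -4.89. The adjoining ORF C189 was also lower, at -4.46 (-5.61 to -3.63). ORF C1156, next to the ribosomal protein gene rplI, had 6 and 742 reads and a ratio of -6.39 (-7.96 to -5.38). The remaining lowest ORFs were truB, a tRNA pseudouridine synthase gene, at -4.77 (-5.98 to -3.90), and ribosomal protein genes and a neighbour of theirs, ORF C1379, at -4.81 (-5.12 to -4.53).

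Ribosomal protein ORFs ranged from -5.20 to -1.20. The lowest were rplC at -5.20 (-5.58 to -4.87), rplL at -5.20 (-5.43 to -4.99) and rpsL at -4.99 (-5.36 to -4.66), followed by rplI at -4.91, rplD at -4.84 and rpsG at -4.74. The median of -3.33 lay below all 10000 random lists, whose central 95% ran from -1.22 to -0.18. Those lists drew ORFs singly, whereas many ribosomal protein ORFs lie in runs of neighbours, such as that from rpsL to rplO. Reads in these genes were plentiful, with 8990 in high and 179 in low phosphate for rplL. With distinct start positions 25 of 50 measured ribosomal protein ORFs were lower, with a median of -1.02.

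The other lists with at least 3 measured members had medians inside the central 95% of their random lists. Chaperones and proteases had 6 of 12 members lower and none higher, with a median of -1.05, including groES (ORF C804) at -2.17, dnaK at -1.85 (-1.96 to -1.74) and grpE at -1.72 (-2.02 to -1.43). For groES (ORF C804), 78.3% of the reads came from sequence present elsewhere in the genome, and its ratio was -2.05 with unique positions only. Counts of distinct start positions gave 0.036, but with 215 and 287 positions in use out of 297 they were near saturation. By that count 3 of 10 members of the list were lower, with a median of -0.14. In the TCA cycle 3 of 8 members were lower, namely sucD at -1.50, mdh at -1.30 and sucC at -1.18, with a median of -0.96. None of the 3 passed 2-fold with distinct start positions, at -0.87, -0.86 and -0.60. For flagellum and chemotaxis 4 of 28 were lower and none higher, led by flgH at -1.57 (-2.15 without the first and last 34 nt), flhA at -1.38 and fliP at -1.25, with a median of -0.56. For the DNA damage response 2 of 10 were lower, uvrA at -1.29 and ruvB at -1.17, with a median of -0.54, and recA had -0.27 (-0.34 to -0.19). With distinct start positions uvrA and ruvB lay within 2-fold, at -0.94 and -0.79. No member of the list for phospholipid synthesis (5 measured, median -0.56) passed 2-fold. The same held for nitrogen fixation and microaerobic respiration, with 5 measured members and a median of 0.37, which was -0.11 with rRNA and tRNA kept in the library sizes. That scaling also put 3 of 5 members for phospholipid synthesis (median -1.05), 16 of 28 for flagellum and chemotaxis (-1.04), 5 of 10 for the DNA damage response (-1.03), 8 of 8 for the TCA cycle (-1.45), 7 of 12 for chaperones and proteases (-1.54), 7 of 13 for ATP synthase and respiratory complexes (-1.07) and 3 of 5 for oxidative stress (-1.20) at least 2-fold lower. It left 4 of 11 members for carbon storage higher, with a median of 0.76, and 4 of 7 for organic phosphorus use, with 2.71. For succinoglycan 11 of 15 stayed higher and 1 was lower, with a median of 2.12. The 1 measured member for galactoglucan, mucR, was lower. The lists for galactoglucan and for iron uptake had 1 measured member each, mucR at -0.74 and rirA at 0.31. A single gene does not stand for its pathway. Whether ORFs without a symbol include other genes of these lists was not checked.

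**Figure D4:**
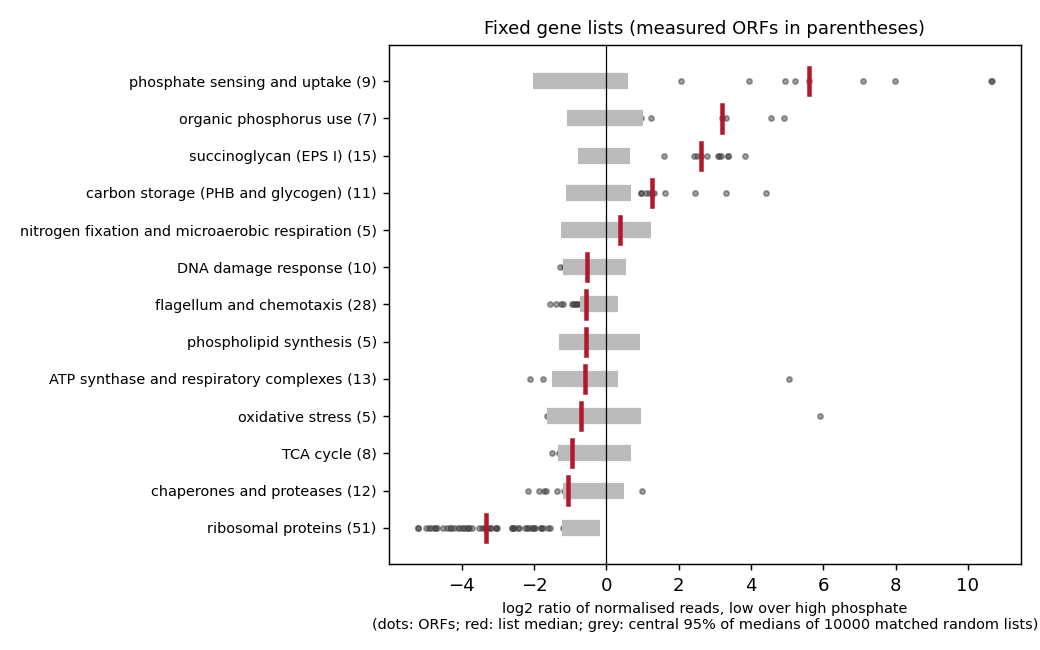
Log2 ratios of measured ORFs (dots) and list medians (red lines) for the fixed gene lists, with the central 95% of medians of 10000 matched random lists (grey bars), pooled libraries. The median for phosphate sensing and uptake lies at 5.61 and that for ribosomal proteins at -3.33, both outside the grey bars.

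Antisense reads were few but some were specific to low phosphate. They made up 3.90% (Wilson interval 3.86 to 3.94%) of ORF reads in the low and 3.29% (3.26 to 3.32%) in the high phosphate pool. Of 129 ORFs with at least 80 antisense reads, 29 were at least 2-fold higher and 29 at least 2-fold lower in low phosphate. With rRNA and tRNA kept in the library sizes these numbers were 18 and 45. Opposite ppx (1292337 to 1293860) there were 393 antisense reads in low phosphate and 0 in high phosphate, at least 178-fold higher against a floor of 3 reads in the pool. Opposite recO (1184359 to 1185138), a DNA repair gene, there were 148 and 0, at least 67.2-fold higher. Antisense reads of ORF B902 on pSymB had a ratio of 4.76 (3.87 to 5.98). The lowest ratios were -4.13 (-6.65 to -2.75) for ORF C1334, from 3 and 83 reads, -3.20 (-3.46 to -2.96) for ORF A123 on pSymA and -2.53 (-3.01 to -2.09) for ORF C446.

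The highest ratios in gaps of at least 100 nt lay next to ORF C1108, phnD and ORF C1209, which were themselves higher in low phosphate. Of 1222 gap strands with at least 80 reads, 354 were at least 2-fold higher and 235 at least 2-fold lower in low phosphate, and 355 were lower with rRNA and tRNA kept in the library sizes. The gap between recO and ORF C1108 (1185139 to 1185443, minus strand) had 883 reads in low and 0 in high phosphate, at least 401-fold higher. The gap between phnE (ORF B854) and phnD (922103 to 922273, minus strand) had 804 and 0, at least 365-fold higher, and the gap between ppx and ORF C1209 (1293861 to 1293996, minus strand) had 213 and 0, at least 96.7-fold higher. The lowest ratio, -7.20 (-13.09 to -5.29), was that of the minus strand between ORF C189 and recF (216563 to 216796), from 1 and 299 reads. A gap beside a tRNA gene (1752676 to 1752817, plus strand) had -5.92 (-6.33 to -5.55), and that between tuf (ORF C1375), an elongation factor gene, and rpsJ (1478451 to 1478592, plus strand) had -4.36 (-4.69 to -4.06).

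The share of ORF sense reads from pSymB was higher in the low phosphate pool, at 15.1% (Wilson interval 15.1 to 15.2%) against 9.50% (9.46 to 9.55%) in high phosphate. The chromosome gave 79.8% (79.7 to 79.9%) and 85.4% (85.3 to 85.4%), and pSymA gave 5.08% (5.04 to 5.12%) and 5.11% (5.08 to 5.15%). Of all reads, with rRNA and tRNA kept, pSymB held 2.23% in low and 2.04% in high phosphate. Without the 10 most abundant ORFs pSymA held 6.12% in low and 5.87% in high phosphate. On pSymB 30.1% of 559 measured ORFs were at least 2-fold higher and 13.1% lower, whereas on the chromosome 14.3% of 2217 were higher and 25.7% lower. On pSymA 16.7% of 293 measured ORFs were higher and 17.7% lower.

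The rRNA operons, 3 copies of a 6495 nt block on the chromosome, kept most reads despite the depletion. They held 80.6% (Wilson interval 80.6 to 80.7%) of the perfectly matching reads in the low phosphate pool and 73.4% (73.3 to 73.4%) in the high phosphate pool. Sense reads in ORFs numbered 936685, or 9.61% of the pool, in low phosphate and 1414050, or 15.0%, in high phosphate.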

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

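The tests of scaling and of start positions were chosen after the result was seen, as was the look at stable RNAs. Those of ORF length and of translation genes were chosen before, but the gene list of the latter was corrected after its first value.

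Reads of stable RNAs, which no comparison of the Results uses, were far above the floor of 3 reads. The low phosphate pool held 49777 reads of tmRNA (ssrA), 42759 of 6S RNA (ssrS), 12570 of the signal recognition particle RNA (ffs) and 7707 of RNase P RNA (rnpB). In the high phosphate pool there were 57749, 40771, 11332 and 4916. The log2 ratios were 0.23 (0.21 to 0.25), 0.51 (0.49 to 0.53), 0.60 (0.56 to 0.63) and 1.09 (1.04 to 1.15).

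Ribosomal protein genes were lower in low phosphate as a list of 51. Under 4 other scalings the list median lay between -3.82 and -3.18, so none of these factors accounts for it. A scaling shifts all ORFs alike, here by -0.49 to 0.15, so the bound of -1 could not be reached. All are relative scalings, so a change in the total of mRNA was not tested. Without the 10 positions with most reads in each ORF and pool, the list median was -3.58. Medians of 2360 reads in high and 153 in low phosphate were left, so the high phosphate reads did not rest on 10 positions alone. The removal weighs more on the sparser low phosphate pool, which moves the ratio away from 0. It therefore cannot decide on reads piled on few start positions. That test replaced a first one on distinct positions, which gave -1.05 over all 51, close to its bound of -1, but is near saturation, with a median of 356 used positions in high phosphate at a median length of 390 nt. Loss of reads from short ORFs is argued against, because 89 other ORFs matched on ORF length and reads had a median of -0.27. Lengths of transcripts were not measured, and many ribosomal protein ORFs lie in long runs of neighbours. Loss of short transcripts was therefore not tested. A growth difference other than phosphate itself cannot be told apart from phosphate, since growth rates are not given in the sources used here and 25 tRNA synthetase and translation factor genes had a median of -1.78, with 17 at least 2-fold lower; the median was -1.71 before glnT, cysQ and cysT, which are neither, were taken off.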

How the results depend on the processing

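The settings for TMM factors, ORF sense totals, unique and distinct positions, the top position, added reads, minimum reads, 4-fold and the title prefix were chosen after seeing the data, as was the setting with rRNA and tRNA kept for antisense reads and gaps. No paired analysis was possible for transcripts because the replicates are pooled in the deposited values. For the same reason DESeq2, limma-voom, leaving out single libraries, adjusted p-values with a fold threshold, camera and fry were not run. Depth limits ORFs with under 80 reads, 3228 of those kept. For the shares of reads per library a replicate block by title prefix could be used; the mean difference in unmatched reads, -8.42 percentage points, is by construction that of the condition means, so it does not test the block.

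The 57 named ORFs gave 798 values under 14 settings: 703 inside the counting interval of the main value, 94 outside it and 1 of opposite sign to a call, groES (ORF C804) at 0.036 with distinct positions. That setting also put 7 other named calls within 2-fold: atpD at -0.30, atpA at -0.41, sucC at -0.60, ruvB at -0.79, mdh at -0.86, sucD at -0.87 and uvrA at -0.94. Settings that change only the minimum number of reads leave the ratio of a named ORF as it was, by construction. Their values count among the 703 inside the interval but do not test the named ORFs. Of 128 list medians under 10 settings, 128 kept their direction and their place inside or outside the central 95% of random lists. The other 52, under 4 scalings, cannot change place, since a scaling shifts lists and random lists alike; 51 kept their direction, and nitrogen fixation was -0.11 with rRNA and tRNA in the library sizes.

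ORFs higher and lower numbered 1323 and 1185 without a filter, 325 and 1168 with rRNA and tRNA in the library sizes (by construction, a factor that favours high phosphate), and 213 and 183 at 4-fold. Lower ORFs numbered 456 on distinct positions, and higher ORFs 300 with at least 200 reads. Median-ratio factors gave a factor ratio of 1.36, as in the deposited values. Antisense counts were 1631 and 1311 without a filter, 18 and 45 with rRNA kept, 79 and 77 at 40 reads and 4 and 3 at 200 reads. Gap counts were 1691 and 1031 without a filter and 163 and 131 at 200 reads, and 355 were lower with rRNA kept.

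Replicon shares moved beyond counting error. With rRNA and tRNA kept, the chromosome, pSymA and pSymB held 96.7%, 1.04% and 2.23% in low and 96.9%, 1.09% and 2.04% in high phosphate. Without the 10 most abundant ORFs they held 78.9%, 6.12% and 14.9%, and 84.8%, 5.87% and 9.35%. With unique positions they held 79.9%, 4.77% and 15.3%, and 85.9%, 4.31% and 9.77%. The PHO box ratio was 1.14 with 5 mismatches, where 22 of 419 shuffled half-sites reached it; it stayed above 95% of them under the other settings. The cause of these shifts was not tested, except where a filter or threshold sets the number of ORFs.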

Other observations

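The blocks of ORFs, the test of read-through and both tests on pstC were chosen after the values were seen; the test of strand assignment was chosen before.

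Runs of at least 5 neighbouring ORFs on 1 strand, all at least 2-fold higher or all lower, also lay outside the fixed lists as matched by symbol. On the chromosome, 7 ORFs at 3199470 to 3206778 had a median log2 ratio of 7.26 and included ORF C3021, with the signature of glycerophosphodiester phosphodiesterases, at 7.78 (6.77 to 9.34). On pSymB, a minus strand run at 970842 to 980242 had a median of 4.87 and a plus strand run at 986105 to 993787 one of 5.13. The first includes ORF B900, which carries calcium-binding RTX repeats and had 1975 reads in low and 32 in high phosphate, a ratio of 6.37 (5.89 to 6.95). Another ORF with RTX repeats, ORF C2038 on the chromosome (2159596 to 2161209), had a ratio of 5.90 (5.34 to 6.59). Of 13 ORFs with these repeats 9 were measured, 6 at least 2-fold higher and none lower, a count made after the values were seen. The unnamed ORF B1439 and ORF B1440 beside phnH had 6.20 and 6.04.

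Lower runs lay on the chromosome except for 1 on pSymA (106949 to 112304, median -2.56). The longest held 25 ORFs at 1474175 to 1488353, from rpsL to rplO, with a median of -3.80; fusA, for elongation factor G, had -4.48 there. Others were ffh to trmD at 3522466 to 3526200 with a median of -3.38, rimP to truB at 267141 to 274420 with -2.25, the suf genes for iron-sulfur cluster assembly at 1874621 to 1879871 with -1.55, and his genes for histidine synthesis at 57909 to 61216 with -1.54.

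The pstC gene is 1485 nt long in the names table and spans 1484 nt here in 2 pieces out of frame. A run of 32 positions (568359 to 568390) near their junction had no read start on the plus strand, where the 100 nt on either side would put 37.4 reads. Of 4421 windows of that length in other ORFs, 1 was empty, 0.0226% (Wilson interval 0.00399 to 0.128%), which makes uneven yield along the transcript less likely. Those windows had at least 1.11 reads per nt on both sides, the lower value beside the run, and could be several-fold denser. The run was also bounded by its empty positions after it was seen. The share may thus understate how often such runs occur, and uneven yield is not ruled out. A candidate explanation is 1 base more in the strain than in the deposited sequence: of 2180 insertions tried in the first piece, 3 lost only positions with 0 reads. These insertions, before 568391, 568392 or 568393, give the same sequence and join the pieces into a frame of 1485 nt without a stop, a hypothesis found and tested on the same reads.

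Antisense reads opposite ppx and recO may come from read-through of the facing ORF C1209 and ORF C1108, 136 and 305 nt away. On that strand in low phosphate, reads per nt were 8.09 in ORF C1209, 1.57 in the gap and 0.258 opposite ppx, and 9.05 in ORF C1108, 2.90 in the gap and 0.190 opposite recO, a ratio of gap to antisense reads of at least 6.07. Among ORFs with a measured facing ORF within 500 nt, other than ppx and recO, that facing ORF was itself at least 2-fold higher for 5 of 10 with higher antisense reads and 6 of 58 others, a count that replaced one over all ORFs. The 58 are not separate measurements, since copies of repeated sequence share divided reads. ORF C2439, ORF C2178, ORF C33, ORF C149 and ORF C2705, for example, each had 153.3 and 247.42 antisense reads in low and high phosphate. Read-through is thus a candidate explanation, and a promoter in the gap or in the end of the facing ORF was not tested and may contribute. Sense reads put on the wrong strand are argued against, since the sense ratios were 1.16 (0.94 to 1.39) for ppx and -0.71 (-1.51 to 0.00) for recO.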
